A study of Drosophila melanogaster with 4 samples.

How the data were processed

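Whole prepupae of Drosophila melanogaster of mixed sex (24 h) from a line expressing dsx fused to enhanced green fluorescent protein were profiled by ChIP-seq with an antibody against the tag, per the labels. The 4 samples are numbered as biological replicates 1 to 4 in the labels, with 1 technical replicate each, and form 1 group. There is no second group, so no groups were compared. The tests of binding are across peaks, genes or sequence windows, and replicates enter as means with their SD. In addition, 11 measures were checked for an outlying replicate with Dixon's ratio at its 95% critical value, from the gap of the highest or lowest replicate to the nearest other over the whole range.

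The peak lists are on dm6, per the deposited text notes. Per the same notes, each replicate's list was called against 1 control file, the pooled list was called on replicates 2, 3 and 4 together, and the reproducible list was derived from their lists by an optimal threshold on the irreproducible discovery rate (IDR). Replicate 1 is not among the inputs of either, per those notes. The aligner, peak caller, its version and the IDR threshold are not given in the sources used here. Each list except the reproducible one holds 30000 summits, which is the length of the list and not a count of binding sites. Such a fixed length lets weak sites enter the list of a weaker sample. The 9154 reproducible summits are the 9154 strongest of the pooled list, so taking that number of peaks from the pooled list gave the same peaks and tested nothing.

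The deposited signal score of each peak is the authors' own value from their peak caller. It is not normalized between lists, so it was used here to rank or describe peaks within a list and in rank correlations. The exception is a check for outlying replicates, which also set the median and highest score of the 4 lists side by side. The deposited −log10 q-value of each peak reaches a common ceiling, which all reproducible peaks share, so it was not used for ranking. The deposited summit position is given in bp from the start of the interval, and summits are printed here as 1-based positions. The score column of the reproducible list held no IDR values, so the stricter alternative took the 4577 peaks with the highest signal value. Sequencing depth per sample was unknown, and intervals cover counting error over peaks only. Signal tracks and control samples were not used here.

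Gene models came from Ensembl release 115 and sequence from the RefSeq copy of the same assembly. Arm lengths were compared between the sequence and the annotation, and all summits lay within them. Peaks were classed by their summits in the order promoter (within 500 bp of a transcription start), 5′ untranslated region, 3′ untranslated region, coding exon, other exon, intron and intergenic. Support by a replicate meant a summit within 100 bp among its strongest 10000, and pairwise overlap used the strongest 5000. Chance levels came from 1000 circular shifts of all summits within each arm. The X to autosome ratio had a bootstrap interval from 10000 draws of blocks of 500000 bp. Motifs were sought on both strands within 50 bp of summits and in windows of the same length centred 500 bp away on each side, and the flank with the higher share was reported. Summits and flanks were compared by two-sided exact McNemar tests, with Benjamini-Hochberg adjustment over 8 motifs or over 8192 sequences of 7 bases. Binomial intervals are exact (Clopper-Pearson) at 95%.

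A gene was bound when a reproducible summit lay within 1000 bp of any of its starts. The background was all 13968 protein-coding genes on the chromosome arms, and 10000 random lists matched on 10 classes of gene length gave the expected number. The 15 lists covered reported Doublesex-regulated genes, sex determination and dosage compensation, ecdysone response, cell death, Hox genes, imaginal disc patterning, cuticle pigmentation, fat body, neurons, muscle, salivary glue with Eig71E genes, ribosomal proteins, chemosensory receptors, germline and testis, and trachea with epithelia. Some genes are in more than 1 list, such as dsx, bab2 and bnl. The noncoding genes roX1 and roX2 and the symbol B had no match among protein-coding genes. The text names the gene nearest to each of the 25 strongest peaks, every gene of the reported list, and at most 4 genes with the strongest peaks in each other list. Nrg, the remaining bound neuronal gene, was named in addition after its values were seen. These rules, lists, tests and thresholds were set before the data were examined, except where stated. The comparison with sequences of the same composition, the motif share per replicate the settings without secondary summits and the exact distribution of length-matched lists were added after seeing the data.

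Alternatives covered the peak list and its threshold, the overlap that counts as shared, the number of peaks per replicate, each replicate left out, distances to starts, the motif, window and flank, block length, window length at dsx and the test without a match on gene length. Procedures were tested on simulated data. With ACAATGT implanted at 4.97% of 9154 simulated summits, a difference of 5.12 percentage points was recovered, and 0.208 with none implanted. The implanted sequence ranked 1 in the search, which called 0 sequences with none implanted. Of random lists of 20 genes, 3.33% had p under 0.05, and all lists of 20 with 13 bound genes were called. Calculations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.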

Results

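Doublesex is the transcription factor at the end of the sex determination cascade of Drosophila melanogaster, and male and female isoforms share its DNA-binding domain. Its genomic binding was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole prepupae of mixed sex, labelled 24 h of age. The flies carried a dsx gene fused at its C terminus to enhanced green fluorescent protein, and chromatin was recovered with an antibody against that tag. The series held 1 group of 4 samples, labelled as 4 biological replicates. Each replicate had its own list of 30000 peak summits. A pooled list of 30000 summits and a list of 9154 reproducible summits in 8775 intervals were derived from replicates 2, 3 and 4, without replicate 1. These 9154 summits are called reproducible peaks here. Read depth was unknown, since the lists hold no read counts. Males and females were mixed, so no comparison between the sexes was possible, and the control samples were not analysed here. Which of the isoforms carried the tag was not examined, so peaks cannot be assigned to the male, the female or both forms.

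The 4 replicates recovered largely the same sites, and the summit 595 bp upstream of dsx itself was the strongest in each of them. On average 81.1% ± 5.08 (SD, n = 4) of the reproducible peaks had a summit within 100 bp among the strongest 10000 summits of a replicate. The share was 74.0% in replicate 1, 81.5% in replicate 2, 85.8% in replicate 3 and 83.1% in replicate 4. After circular shifts of the peaks along each chromosome arm the highest share in any replicate was 2.24%. All 4 replicates held 4867 of the peaks (53.2%) among their strongest 10000, and 57 peaks (0.623%) were held by none. For pairs of replicates, 71.2% ± 4.81 (SD, n = 6 pairs) of the strongest 5000 peaks of one were shared with the other. The values ranged from 65.1% for replicates 1 and 4 to 78.2% for replicates 3 and 4. The Spearman correlation of signal values across reproducible peaks averaged 0.742 ± 0.053 (SD, n = 6 pairs), a description across peaks, which are not independent replicates. Replicates 2, 3 and 4 contributed to the reproducible list themselves, so only the support in replicate 1 comes from a sample outside it.

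**Figure D1:**
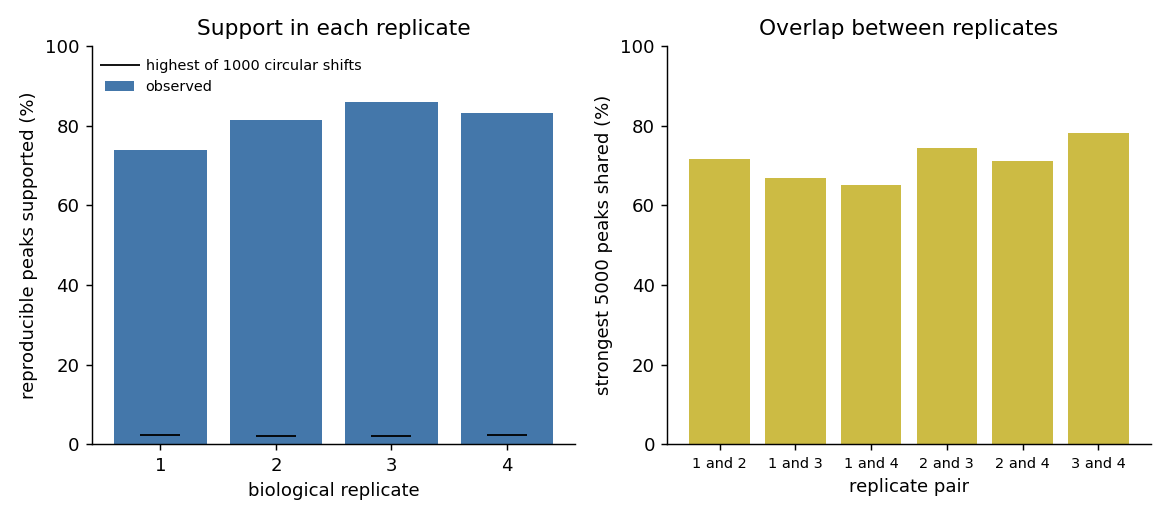
The left panel gives the percent of the 9154 reproducible peaks with a summit within 100 bp among the strongest 10000 of each replicate (bars), and the highest value of 1000 circular shifts (black lines, at most 2.24%). The right panel gives the percent of the strongest 5000 peaks shared by each pair of replicates, which lies between 65.1% and 78.2%.

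The strongest peaks lay upstream of dsx itself, near the rhodopsin gene Rh5 and in the insulin receptor gene InR. The first in rank was 595 bp upstream of the dsx transcription start (gene FBgn0000504 at 3R 7924323 to 7967408, minus strand), with its summit at 3R 7968003 in dm6 and an authors' signal value of 68022. A further summit in the dsx promoter, at 3R 7967084, ranked 20. The second strongest peak, at 2L 12010400 with a signal value of 49509, lay in intergenic sequence 2022 bp downstream of the start of Rh5, whose rhodopsin is a light sensor of photoreceptors. The third was in an intron of InR (3R 21608447, signal value 29541). Next in rank were Sesn, a stress-induced inhibitor of TOR signalling, with a summit 576 bp upstream of its start, and AdipoR, the adiponectin receptor gene, with a summit 59 bp upstream of its start.

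E2f1, a regulator of cell cycle entry, held the sixth strongest peak in an intron (3R 21650737, signal value 18755). The seventh lay 1194 bp upstream of shd, which encodes the enzyme that makes the active form of the moulting hormone ecdysone (3L 14613264, 16383). A peak at 3L 1118641, 17552 bp upstream of bab1 (13425), was ninth in rank; bab1 encodes a repressor of abdominal pigmentation. Among the remaining 25 strongest were peaks near dmrt99B, a relative of dsx with the same type of DNA-binding domain (3R 29691176, signal value 9530), near mtSSB, which encodes a mitochondrial single-stranded DNA-binding protein (3R 16205561, 12260), and near Glut4EF (3R 9874157, 9976). Further genes nearest to these peaks were bun, a TSC22-type transcription factor gene, Fhos and coro, both regulators of the actin cytoskeleton, blow, needed for myoblast fusion, the hexokinase gene Hex-C, the receptor tyrosine phosphatase gene Ptp10D and the UDP-galactose transporter gene Ugalt. The peak assigned to Hex-C lay 4991 bp upstream of it within an intron of Fs, the follistatin gene. The less characterised genes CG13073, CG18404, CG12362, CG43149, CG46443 and CG43131 were nearest to the rest.

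Of the 25 strongest peaks, 13 were intergenic, 6 lay in introns, 5 within 500 bp of a transcription start and 1 in a coding exon, that of CG13073. Of these peaks, 23 of the 25 were among the strongest 50 peaks of all 4 replicates. The exceptions were the peaks at coro, at rank 84, and CG46443, at the lowest rank of 104, both in replicate 1. The 25 were chosen by their signal in the pool of replicates 2, 3 and 4, so only replicate 1 is outside that choice. The peaks at dsx, Rh5 and InR ranked 1, 2 and 3 in each replicate. A peak was assigned to the protein-coding gene with the nearest start, and no expression data were used to link peaks to genes.

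Summits were dense along the dsx locus. In dsx and 5 kb on each side there were 30 reproducible summits. Some of these lay under 260 bp to the higher-coordinate side of a stronger summit, such as 3R 7969361 beside 3R 7969158. The 30 are therefore not all separate sites. Next to the 2 summits at the start, the strongest was in an intron at 3R 7957208 (signal value 6025, rank 43). ACAATGT, the core of the known Doublesex binding sequence, lay within 50 bp of 2 of the 30 summits, at 3R 7954683 and 3R 7961584. The longer degenerate consensus RNNACWAWGTNNY lay at 7 of them, the strongest summit included. The 50 kb around dsx held 54 summits of the pooled list against a median of 9 over windows of that size, and 99.85% of the 2648 windows held fewer. Reads from the tagged copy of dsx map to this same region, and the labels do not say whether that copy adds to the endogenous gene or replaces it.

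**Figure D2:**
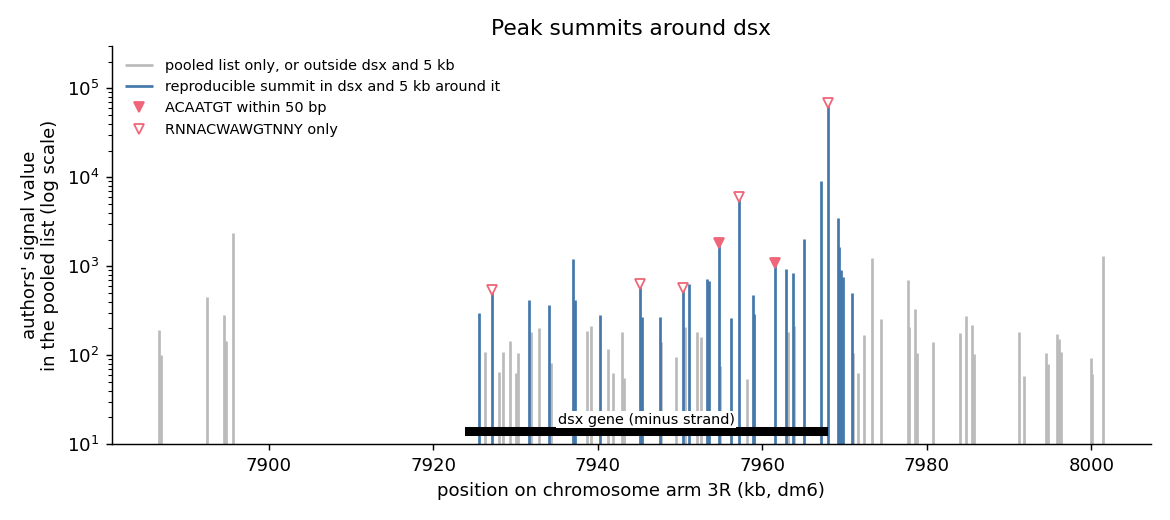
Summits of the pooled list around dsx on 3R (position in kb, dm6) against the authors' signal value on a log scale; blue lines are the 30 reproducible summits in dsx and 5 kb on each side, grey lines are other summits. Filled triangles mark the 2 summits with ACAATGT within 50 bp and open triangles those with only the longer consensus; the highest line is the summit 595 bp upstream of dsx.

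Reproducible peaks lay mostly in promoters and introns and hardly at all in coding sequence. A transcription start was within 500 bp of 3338 summits (36.5%), a share 2.69 times the 13.6% that shifted peaks gave on average. No shift exceeded 15.5% (two-sided permutation p = 0.002, the smallest that 1000 shifts can give). Introns outside promoters held 3851 summits (42.1%, against 39.5% of the genome) and intergenic sequence 1641 (17.9%, against 27.2%). Coding exons made up 13.1% of the genome but held 35 summits (0.382%), and 3′ untranslated regions held 88 (0.961%, against 5.06%). These shares are set against the genome's composition and, apart from that of promoters, were not tested.

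The density of peaks on X did not differ detectably from that on the autosomes. There were 65.0 reproducible peaks per Mb on X and 69.7 per Mb on 2L, 2R, 3L and 3R together. The ratio of 0.933 had a 95% bootstrap interval of 0.778 to 1.10, which includes equal density. The median signal value was 451.7 on X and 466.0 on these autosomes. Neither density nor signal was corrected for the number of X copies in animals of mixed sex, so equal binding per copy was not tested. Among the large arms, 3L had the highest density with 74.7 per Mb. Chromosome 4, which is largely heterochromatic, had 29 peaks, or 21.5 per Mb, and no summit was listed on Y.

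The Doublesex core sequence was concentrated at peak summits. ACAATGT, on either strand, lay within 50 bp of 738 of the 9154 summits (8.06%, 95% exact binomial interval 7.51 to 8.64, which covers counting error only). In windows of the same length 500 bp away it lay in 1.45%, so that the share at summits was 5.55 times higher (exact McNemar test, two-sided, p = 1.47e-105). The longer consensus RNNACWAWGTNNY was found at 6.07% of summits and 1.19% of flanks (exact p = 8.97e-76). ACAAAGT, which differs from the core at a single base, was found at 6.84% of summits and 2.12% of flanks (exact p = 1.65e-55).

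A search over all 8192 distinct 7-base sequences, with no preset motif, gave ACAATGT as the first and ACAAAGT as the second by p. After Benjamini-Hochberg adjustment 473 sequences were more frequent at summits than in the flank with the higher share. Another 1333 were less frequent at summits, a count that the choice of the higher flank favours. Of the 473, 286 had at most 1 G or C, and GC content was 38.3% within 50 bp of summits against 42.2% in the upstream flank. None of the 419 other sequences with the base composition of the core reached its ratio of summit to flank share. Their median ratio was 1.08 and the highest was 3.12, for CATTGTA, which overlaps the core by all but one base. GAGAG, bound by the GAGA factor Trl, was at 15.4% of summits and 13.4% of flanks (exact adjusted p = 0.000231). TATCGATA, of the class bound by the promoter factors DREF and BEAF-32, was at 0.776% and 0.317% (exact adjusted p = 6.43e-05). The E-box CACGTG was at 0.808% of summits and at 1.18% and 1.03% of the flanks. A comparison with the higher flank favours a lower share at summits, so no depletion is called here. The Zelda site CAGGTAG (0.393% against 0.590%, exact adjusted p = 0.0756) and the repeat CACACAC (5.05% against 4.77%, exact adjusted p = 0.412) did not pass the threshold.

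**Figure D3:**
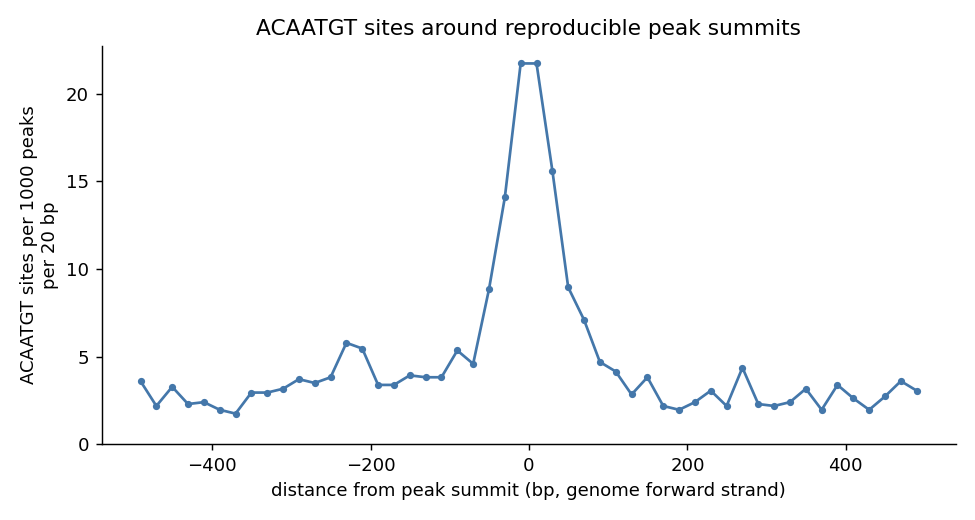
ACAATGT sites per 1000 reproducible peaks in bins of 20 bp, by distance from the summit in bp along the forward strand of the genome. The frequency is highest in the bins on either side of the summit, with 21.7 sites per 1000 peaks each, and a smaller rise of 5.79 lies between 240 and 221 bp on the lower-coordinate side.

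Stronger peaks held the core more often. ACAATGT was within 50 bp of 13.9% of the strongest 1831 summits (12.3 to 15.5), of 8.03% of the next 1831 and of 5.41% of the weakest 1830 (4.42 to 6.55). Of the strongest 100 peaks 38% held it (28.5 to 48.3), and of the strongest 25, 13 did, among them those near Rh5, InR, AdipoR, shd, bab1, Glut4EF and dmrt99B. The summits at the dsx start, Sesn and E2f1 did not. The Spearman correlation of motif presence with signal value across peaks was 0.106 (two-sided permutation test with 100000 resamples, p = 1e-05, the smallest it can give). The median signal value was 621.8 with the core and 455.1 without it. Each replicate's strongest 5000 peaks held the core at 7.26%, 8.60%, 9.68% and 10.3% of summits in replicates 1 to 4, a mean of 8.97% ± 1.34 (SD, n = 4).

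**Figure D4:**
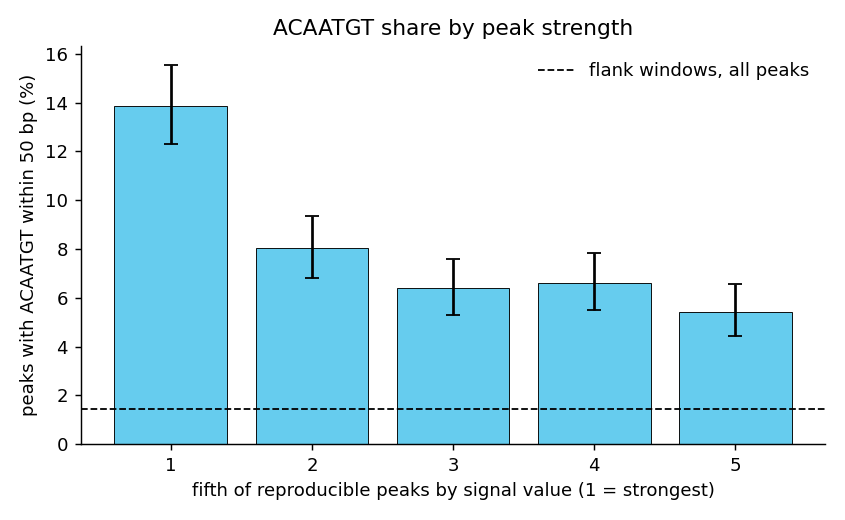
Percent of reproducible peaks with ACAATGT within 50 bp of the summit (bars, with 95% exact binomial intervals) in 5 classes of nearly equal size by the authors' signal value, from the strongest (1) to the weakest (5). The share goes from 13.9% to 5.41%, and the dashed line is the share of 1.45% in flank windows.

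The core was more common away from promoters. It was at 571 of 5816 distal summits (9.82%, 9.06 to 10.6) and at 167 of 3338 promoter summits (95% exact interval 4.29% to 5.80%), an odds ratio of 0.484 (Fisher's exact test, two-sided, p = 4.72e-17). Both classes were above their flanks (exact McNemar p = 2.56e-91 and 4.38e-14). Of the reproducible summits, 713 lay under 260 bp to the higher-coordinate side of a stronger summit, and 2.10% of these held the core. Without them, a setting chosen after seeing the data, the share over all summits was 8.57%.

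Ecdysone response and cytosolic ribosomal protein genes were bound more often than genes of their length, and chemosensory receptor, neuronal and germline genes less often. Of 13968 protein-coding genes, 3654 (26.2%) had a reproducible summit within 1 kb of a transcription start. The share went up with gene length, from 10.7% in the shortest of 10 equal length classes to 52.7% in the longest. Each of 15 lists was therefore compared with 10000 random lists of the same size, matched on these length classes. The comparison was a two-sided permutation test with Benjamini-Hochberg adjustment over the lists. A gene could be bound at any of its starts, and the number of starts per gene was not matched. Length within a class was not matched either, so the part of both in any excess was not examined.

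Of 24 regulators of the ecdysone response, which drives metamorphosis, 17 were bound against 10.6 on average in matched lists (permutation adjusted p = 0.0282). The strongest of these peaks were at usp and EcR, which encode the ecdysone receptor pair, and at the early response genes Eip75B and Eip93F. The signal value was 2224 at usp (X 2042181, in its promoter, within the span of Actn and CG4313 as well), 1652 at Eip75B, 1212 at EcR and 1126 at Eip93F. None of the 17 peaks held ACAATGT. The core was at only 167 of 3338 promoter summits, so 17 peaks are too few to show a lower share. Among 36 genes of imaginal disc patterning and signalling 24 were bound (16.7 expected, permutation adjusted p = 0.0495). They included the Dpp receptor gene tkv (signal value 2020), the homeobox gene al, with the core at its promoter summit (2L 378172, 1365), and aos and rho of the Egfr pathway (1148 and 1127). This call was at the edge of the threshold, since the exact distribution of matched lists, added after seeing the data, gave an adjusted p of 0.0511. It was also lost with the strongest 4577 peaks and over gene bodies, and the ecdysone call was lost with those peaks and within 500 bp of starts.

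Cytosolic ribosomal protein genes had the largest excess among the lists bound more often, with 47 of 92 bound against 16.4 expected (permutation adjusted p = 0.0015; the unadjusted p of 0.0002 is the smallest that 10000 draws can give). RpS19b (signal value 1739), RpS28b (994.6), RpL34b (958.6) and RpL3 (795.7) had the strongest peaks, and the RpS19b summit lay 930 bp upstream in an intron of CG5854. The strongest peak of 1 of the 47 bound genes held ACAATGT.

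Genes of odorant, gustatory and ionotropic receptors were nearly free of peaks, with 3 of 179 bound against 38.7 expected (permutation adjusted p = 0.0015). The exceptions were Ir60a (signal value 1878, in an intron of nord), Or65a (848.9, with the core) and Gr77a (296.2). None of 24 germline and testis genes was bound (6.58 expected, permutation adjusted p = 0.002, a call lost when the strongest 4577 peaks were used). Of 26 neuronal genes 5 were bound (12.1 expected, permutation adjusted p = 0.0240): elav and Rbp9, which encode RNA-binding proteins of neurons, insc, which orients neuroblast divisions, the synaptotagmin gene Syt1 and the adhesion molecule gene Nrg. The elav summit (2344) lay 290 bp upstream of its start, within the arginase gene arg. The neuronal call was lost with the strongest 4577 peaks (permutation adjusted p = 0.276), within 500 bp of starts (0.0910) and in Fisher's exact test without a match on length (0.694).

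The other lists did not pass the threshold. Sex determination and dosage compensation genes were bound in 8 of 23 cases (7.10 expected), with dsx, gro, msl-1 (746.1) and the master gene Sxl (709.9) strongest. Cell death regulators were bound in 6 of 14 cases (4.06 expected), among them the caspase inhibitor Diap1 (2118) and its antagonists hid (1951) and rpr (473.5), and the caspase gene Drice (600.2). Hox genes and cofactors were bound in 3 of 12 cases (5.82 expected): hth (880.0), Abd-B (686.1, with the core) and abd-A (338.1). Of 22 muscle genes 7 were bound (8.44 expected), led by Msp300 (4856, rank 77), Tm1 (1543, with the core), Zasp52 (1522) and sls (764.0). Of 17 tracheal and epithelial genes 7 were bound (7.13 expected), with crb (2214), grh (1442), sty (1098, with the core) and dysf (819.5) strongest. Cuticle pigmentation genes were bound in 6 of 17 cases (6.68 expected), led by speck (1216), bab2 (650.6), bi (520.4) and kay (502.6). Fat body genes were bound in 4 of 15 cases (4.48 expected), namely Mtp (478.3), srp (346.6), apolpp (336.8) and Ilp6 (303.5). None of 20 salivary glue and Eig71E genes was bound (2.55 expected, permutation adjusted p = 0.257). Adjusted p in the other 7 of these lists, and in that of reported targets, was between 0.324 and 1.

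**Figure D5:**
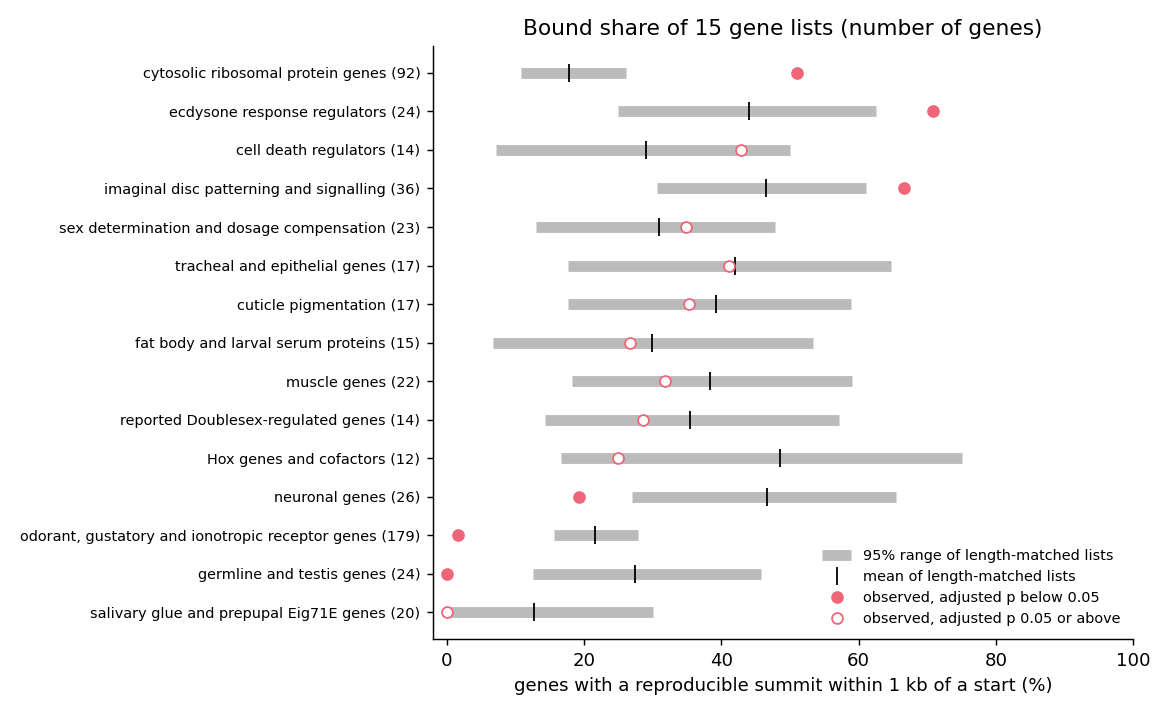
Percent of the genes of 15 lists with a reproducible summit within 1 kb of a transcription start (points, number of genes in brackets), against the mean (black ticks) and 95% range (grey bars) of 10000 length-matched lists. Filled points passed the adjusted threshold: ribosomal protein, ecdysone and disc patterning genes (adjusted p of the last 0.0495) lie above the range, and neuronal, receptor and germline genes below it.

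Genes known as targets of Doublesex showed no detectable difference from genes of their length near their starts, with 4 of 14 bound against 4.95 expected (permutation adjusted p = 1). The ratio of 0.808 changed sides without passing the threshold, to 1.33 with the strongest 4577 peaks, 1.20 within 2 kb of starts and 1.35 over gene bodies. The 4 were dsx, bab2, bnl, the FGF ligand gene of tracheal and genital disc growth, and the cell death gene rpr. The signal value was 650.6 for bab2 (3L 1177198, 78 bp downstream of its start), 637.1 for bnl (3R 19836915) and 473.5 for rpr. Another 4 had peaks in introns. The pigmentation gene bab1 had 16 reproducible summits in its body, 2 of them with ACAATGT, the strongest at 3L 1089412 (1793). Wnt2 had 3 (strongest 585.3), dac 2 (strongest 316.1) and the Hox gene Scr 1, with the core (3R 6842436, 330.0). The much stronger peak 17552 bp upstream of bab1 (3L 1118641, 13425, rank 9, with the core) lay outside the distances used. It was therefore not counted for bab1.

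No reproducible summit was listed in or within 1 kb upstream of the yolk protein genes Yp1 and Yp2, the pheromone enzyme genes Fad2 and eloF, the taste receptor gene Gr68a or the relaxin-type receptor gene Lgr3. The nearest was 1323 bp from Fad2, 3523 bp from Lgr3, 12269 bp from Yp1, 13055 bp from eloF, 15131 bp from Yp2 and 34825 bp from Gr68a. The pooled list had a weaker summit in this range at Fad2 (131.5), below the median of 148.8 in that list. It also had 1 in range of both Yp1 and Yp2 (203.8), above that median. A list of the strongest 30000 summits sets no lower limit on binding at these genes.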

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

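The tests of the height of the dsx peak, of the longer consensus at dsx and of paired summits were chosen after the results were seen; the other tests were set beforehand. Over 11 measures compared across the 4 replicates, a single replicate stood apart in 2. The nominal rate of about 1 in 20 per measure is no guide here, since the measures are related. Replicate 1 listed 25 summits on the mitochondrial genome and the other replicates none. With none in the others, any such summits in replicate 1 would have stood apart. The strongest of the 25 ranked 16 in its list, and the ranks given for replicate 1 count these summits. The median signal value was 30.1 in replicate 1, below the 44.7 to 46.7 of the others. This score is not normalized between lists, so the gap can be one of scale and is no measure of binding.

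The strongest peak of every list lay upstream of dsx, the gene that carries the tag. An extra copy of the region in the tagged line may raise signal over the whole locus, and 99.85% of windows of 50 kb held fewer pooled summits than the one at dsx. A copy that raised the whole locus evenly would not set a single summit apart. The strongest peak was 106.4 times the median of the other reproducible summits of the locus. This argues against such an even rise as the whole cause of its height. The extent of any extra copy is not known, and the peak was known to be the highest when the test was set. A copy of a shorter segment therefore stays open. Binding of the tagged protein at core sites of its own gene stays open: ACAATGT was at 6.67% of the 30 summits (exact interval 0.818 to 22.1), which holds both the flank share and that of all peaks. The longer consensus was at 23.3% of them (9.93 to 42.3), above its 1.19% in flanks and 6.07% over all peaks. Binding at such sites would give this, which does not exclude a part of the extra copy. Both intervals count summits under 260 bp apart as separate, though some are likely secondary. The control's signal at dsx was not analysed here.

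Ribosomal protein promoters were bound 2.87 times as often as matched genes and, like other promoter summits, seldom held the core. Recovery of active promoter chromatin without the motif was taken to predict a lower share than at other promoters. ACAATGT was at 3.45% of the 58 summits near these genes and at 5.03% of other promoter summits (Fisher's exact test, two-sided, p = 1). No difference was seen, and the 58 summits were few. Most other promoter summits lack the core too and could share that cause, so the contrast cannot decide the question. Whether Doublesex acts on these genes was not tested, since the group has no contrast.

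Many reproducible summits came in pairs about 200 bp apart, with 729 pairs under 260 bp and none under 199 bp. The stronger summit had the lower coordinate in 97.8% of these pairs (96.5 to 98.7), against 46.3% of neighbours 600 to 1000 bp apart. Binding to DNA has no preferred strand of the reference genome, so the weaker member is likely a secondary summit of the peak caller. The core was at 2.10% of the 713 weaker members and at 11.8% of their stronger partners. Paired binding sites would not give this one-sided order, and no biological explanation was tested.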

How the results depend on the processing

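The settings without secondary summits, the count of intervals and the exact distribution of length-matched lists were chosen after seeing the data. Of the alternatives, 21 used the strongest peaks of the pooled list, which are the same 9154 peaks, and say nothing of stability. Of the other 163 alternatives over 26 results, 120 left direction and threshold, or size within its spread, as they were. These included every such alternative for the promoter share, X density, the signal correlation between replicates, the core at summits, by strength and by promoter, and the 7-base search. The same held for ribosomal protein and receptor genes. Depth per sample was unknown, so its effect could not be examined. The cause was not tested except where the setting itself sets the number. The number of reproducible peaks was 4577 by the stricter threshold on signal value, and 4867 when all replicates had to hold a peak; demanding 3 replicates in turn gave 5229 to 5814. Replicate support was 95.2% for these strongest 4577, 69.6% within 50 bp, 87.8% within 250 bp, 68.9% by mutual overlap of intervals, 50.5% in the strongest 5000 and 92.9% in all 30000. Pairwise overlap was 58.9% within 50 bp, 77.7% within 250 bp, 64.2% by intervals, 77.9% for the strongest 1000 and 65.99% for 10000. At dsx, 99.56% of windows of 20 kb and 97.96% of windows of 100 kb held fewer summits.

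Gene lists are given as the number or share bound over that expected. With the strongest 4577 peaks, the ecdysone list was at 1.39, disc patterning at 1.19, neurons at 0.410 and germline at 0, all no longer past the threshold. Disc patterning also lost its call over gene bodies (1.33) and with the exact distribution (1.44, adjusted exact p = 0.0511). New random draws moved it over the threshold with the same peaks (1.43) and without secondary summits (1.44), where the exact adjusted p was 0.0495. Ecdysone (1.61) and neurons (0.473) lost theirs within 500 bp of starts. Without a match on length the ratio was 0.735 for neurons, no longer past the threshold, and 0 for glue and Eig71E genes, now past it (Fisher's exact test, adjusted p = 0.00936). Lists that did not pass changed sides of 1 without passing. Reported targets went from 0.808 to 1.33 with the strongest 4577, 1.20 within 2 kb, 1.35 over gene bodies and 1.09 without the match. Pigmentation went from 0.899 to 1.04 within 500 bp, 1.07 within 2 kb, 1.02 over bodies and 1.35 without the match. Trachea went from 0.982 to 1.16 with the strongest 4577, 1.05 over bodies and 1.57 without the match. Fat body reached 1.02 and muscle 1.22 without the match.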

Other observations

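The gene families, the insulin list and their tests were chosen after the peak lists were seen. Of 11 families taken by gene symbol, cytochrome P450 genes, which include enzymes of steroid and xenobiotic metabolism, were bound less often than length-matched genes. A summit within 1000 bp of a start was found in 7 of 85 cases against 20.5 expected (permutation test, adjusted p = 0.0022 over 11 families). Cyp6u1 and Cyp310a1 had the strongest peaks among the 7. The peak of rank 7, with the core, lay 1194 bp upstream of the ecdysone enzyme gene shd. It was beyond the 1000 bp limit and was not counted for shd. The lower number thus holds near starts only and does not show that genes of steroid enzymes lack binding. CPR cuticle protein genes (6 of 70, 13.2 expected, permutation adjusted p = 0.0946) and Osiris genes (1 of 25, 5.74 expected, permutation adjusted p = 0.0946) did not pass. The same held for odorant-binding protein genes (3 of 51, 7.51 expected, permutation adjusted p = 0.194) and Jonah proteases (0 of 16, 2.17 expected, permutation adjusted p = 0.2997). Housekeeping families other than cytosolic ribosomal proteins did not pass either, with 17 of 73 mitochondrial ribosomal protein genes bound (10.7 expected, permutation adjusted p = 0.153), 12 of 48 proteasome genes (8.79 expected, 0.350), 11 of 40 genes of respiratory complex I (7.33 expected, 0.2997) and 14 of 44 translation initiation factor genes (11.5 expected, 0.462). Nuclear receptor genes outside the ecdysone list were bound in 6 of 10 cases (3.82 expected, 0.313), with Hnf4, Hr96 and ERR among them.

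Relatives of dsx with the same type of DNA-binding domain differed in their peaks. Near dmrt99B there were 3 reproducible summits within 5 kb, 1 with ACAATGT, and near dmrt11E there were 2, the stronger at rank 1021. None lay within 5 kb of dmrt93B. As a family of 4 with dsx, 3 were bound (1.35 expected, permutation adjusted p = 0.2997).

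Several of the strongest peaks lay at genes of insulin and nutrient signalling, namely InR, Sesn, AdipoR and Glut4EF, and Doublesex might bind this class as a whole. In a list of 41 insulin and TOR pathway genes, without those 4, 19 of 37 had a reproducible summit in the gene body or 1 kb upstream. Length-matched lists gave 14.6 on average with a central 95% range of 9 to 20 (permutation test, p = 0.157). The number was above the mean but inside the range, so an excess over the class stays undecided. Among the 19 were Akt, foxo, Thor, S6k, Ilp6 and ImpL2.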
